A study of Mus musculus with 9 samples.

How the data were processed

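Total RNA of whole lung was purified with oligo(dT) beads for mRNA, made into libraries that underwent DSN processing (treatment with duplex-specific nuclease), and sequenced on the DNBSEQ platform, per the labels. DSN lowers abundant transcripts, and how evenly it acted between libraries cannot be seen from TPM, which limits the values of abundant genes such as Saa3, Lcn2, Retnla and the haemoglobin genes. A single table of TPM values computed by the authors was deposited, with 1 column for each of the 9 libraries and 18875 genes, 400 of which were never above 0. Per the submitters' processing notes, HISAT2, Bowtie2, RSEM and DESeq2 were used, with no role or version given, and the build was GRCm38.p6, which the labels name for 8 of the 9 samples. The column sums of the deposited table differ by at most 1.09 TPM, so read numbers cannot be recovered and no interval for counting error was computed. Count models such as those of edgeR and DESeq2 were not used here, since they need counts.

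Groups, comparisons, gene lists and alternatives were fixed before the data were examined. Genes with at least 1 TPM in at least 3 libraries were tested (13991 genes), and the other 4884 were left out of the tests. Values as deposited were taken as log2(TPM + 1) and fitted with limma 3.58.1 in R 4.3.3 over the 3 groups, with 6 residual degrees of freedom and eBayes moderation with an intensity trend. The 3 pairwise comparisons were tested two-sided, with Benjamini-Hochberg adjustment over all tested genes in each and a threshold of 0.05 on adjusted p. A fold change is given as the difference of group means on this scale, and a rank test of 3 against 3 libraries could reach no exact p under 0.1. Python 3.11.15 was used for annotation and figures.

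Gene lists for 52 pathways and cell types with at least 5 tested members were tested with camera from limma, with a preset correlation of 0.01 and adjustment over the lists of a comparison, and again with the correlation estimated from the data. Lists for basal and squamous epithelium (1 tested member) and for thymus and immature lymphocytes (3 tested members) were too small to test, and a list of mitochondrially encoded genes had none in the table. Genes are named by rule, and not all are printed. For each comparison these are the 10 largest increases and decreases among changed genes whose groups do not overlap, without predicted, RIKEN and pseudogene names and immunoglobulin and T cell receptor segments. Added to them are up to 3 members with the smallest p of each called list, the genes of a fixed exposure panel that passed, and always Nfe2l2, Keap1, Nqo1, Hmox1, Cyp1a1, Il6, Col1a1 and Acta2. Any other gene is said to have been named after its values were seen, or stands as a contrast to its value in another comparison. Positions come from the annotation of GRCm38.p6, in which 18386 genes (97.4%) were matched by gene ID and 489 were not.

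Alternatives were log2(TPM + 0.1), no filter on low values, a mean TPM of at least 5, median-ratio scaling (size factors from genes above 0 in all libraries with a mean TPM of at least 5), quantile normalization, a fit of the 2 compared groups alone, the replicate number as a block, no intensity trend, robust eBayes, array weights, ranks in camera, and leaving out each library in turn. A correction for transcript length and GC content was added after the short-term libraries were seen to fall with length. It subtracts from each library a natural spline in length and a natural spline in GC content, each with 5 degrees of freedom, fitted together to that library's difference from the mean of all libraries, and leaves out 221 tested genes without a known transcript length. Overlap of the changes against the shared PBS libraries was set against 100 simulations of groups without effect (seed 11). The pipeline was tested on simulated data with 200 changed genes among 13991. At a log2 change of 1 it recovered 81.0% for long-term PM2.5 against PBS, 75.0% for short-term PM2.5 against PBS and 79.0% for long-term against short-term PM2.5, and at 2 it recovered 100% in each. False calls were 6.22%, 3.31% and 4.79% of the calls, in the same order. With a length trend added to the simulated short-term libraries, false calls were 95.2% for short-term PM2.5 against PBS and 95.0% for long-term against short-term PM2.5, and camera called 7 and 9 lists, against 0 without the trend. After the correction false calls were 3.33% and 5.85%, and camera called 0 lists in each.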

Results

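Whole lungs of wild-type BALB/c mice, an inbred laboratory strain, were profiled by mRNA sequencing in 9 libraries, 3 in each of 3 groups. Mice of the long-term group received PM2.5, fine airborne particulate matter, through the nose at 10 mg/kg, 6 times at intervals of 3 days. Mice of the short-term group received the same dose 1 time. The labels describe the PBS group as a long-term exposure to PBS. It therefore matches the long-term group in duration, and the short-term group has no control of its own duration here. The time between the last dose and the collection of the lungs is not given in the sources used here. The series title names pulmonary fibrosis, acute lung injury and the antioxidant function of Nrf2, a transcription factor that induces antioxidant and detoxification enzymes. Expression was given in TPM, a share of transcripts corrected for their length, for 18875 genes, of which 13991 reached 1 TPM in at least 3 libraries and were tested. TPM keeps no record of the read number. The labels do not say that the 3 samples of a group came from separate mice, so the p-values measure only the spread between these samples.

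Spearman correlations across the tested genes, which are not independent replicates, were 0.960 to 0.993 between libraries of the same group and 0.893 to 0.976 between libraries of different groups. The short-term libraries were the most uneven, at 0.960 to 0.988, against at least 0.988 within the other groups. They also detected fewer genes, with 12560, 13414 and 13175 genes at 1 TPM or more against 13534 to 13930 in the other 6 libraries. Long transcripts were lower in all 3 of them. Against the PBS mean, the median log2 difference of the genes with the longest transcripts minus that of the genes with the shortest was -1.43 in short-term replicate 1, -0.65 in replicate 2 and -0.87 in replicate 3. The same value was -0.20 to -0.13 in the long-term libraries and -0.077 to 0.064 in the PBS libraries. The first principal component, with 66.2% of the variance, separated the short-term libraries from the others, with short-term replicate 1 farthest out, and the second, with 18.3%, separated long-term PM2.5 from PBS.

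**Figure D1:**
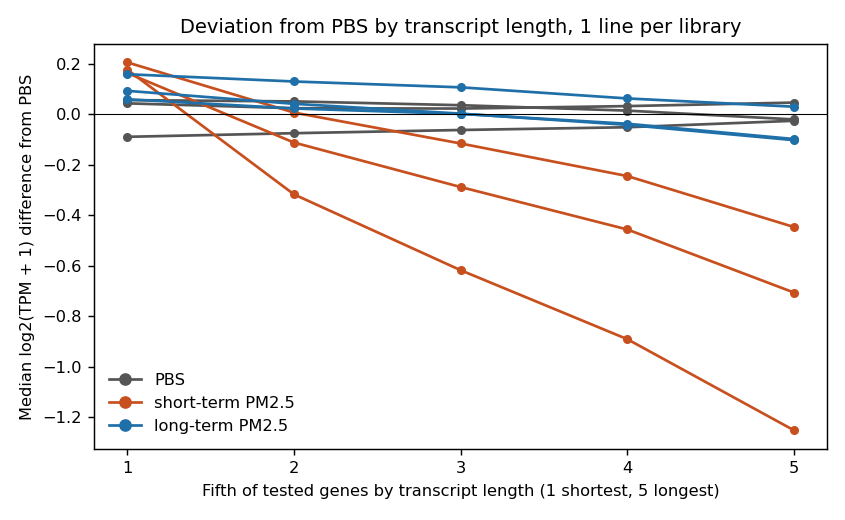
Median log2(TPM + 1) difference from the PBS mean (vertical axis) for tested genes sorted by transcript length into 5 bins (horizontal axis, 1 shortest to 5 longest), with 1 line per library. The lines of the 3 short-term libraries descend with length, with a longest minus shortest difference of -1.43, -0.65 and -0.87, and those of the long-term libraries descend less, with -0.13, -0.20 and -0.16.

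Long-term PM2.5 against PBS asked what repeated instillation of particles changed in the lung. Genes of mucus-producing airway cells, ciliated cells, lipid-laden macrophages and dividing cells were higher after long-term PM2.5, and genes of blood vessels, heat shock proteins and haemoglobin were lower. These are calls of gene lists with a preset correlation, and with an estimated correlation they had adjusted p from 0.132 to 0.276, so that none was kept. Retnla, which encodes a small secreted protein of alternatively activated macrophages and airway epithelium, showed the largest change on the log2(TPM + 1) scale, from 50.9 ± 8.46 TPM with PBS to 6663 ± 364 TPM (mean ± SD, n = 3), a log2 fold change of 7.01 ± 0.13 (± SE). Clca1, a secreted product of goblet cells, went from 0.350 ± 0.173 to 160.4 ± 35.6 TPM, and Mmp12, macrophage elastase, from 5.04 ± 0.339 to 230.5 ± 37.1 TPM. On the log2(TPM + 0.1) scale the change of Clca1 (8.52) was larger than that of Retnla (7.04). Hspa1a, which encodes the inducible heat shock protein Hsp70, fell from 284 ± 66.2 to 44.5 ± 20.7 TPM, the largest decrease on the log2(TPM + 1) scale.

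Of 13991 tested genes, 1571 changed in the limma test at an adjusted p under 0.05, 1330 higher and 241 lower with long-term PM2.5. Of these, 536 of the higher and 20 of the lower genes moved by at least 1 on the log2(TPM + 1) scale, which understates the change of genes with low values. The 3 libraries of 1 group did not overlap those of the other in all 1571, and in 43.2% of all tested genes, where chance gives 10%. Large increases were also seen for Gpnmb (log2 fold change 4.09) and Ctsk (3.80), a glycoprotein and a lysosomal protease of macrophages, for the chemokines Ccl8 (3.77) and Cxcl3 (3.36), and for Gp2 (3.46), the anion exchanger gene Slc26a4 (3.46) and Speer4c (3.34). Large decreases besides that of Hspa1a (-2.75) were those of Hspa1b (-2.70), the haemoglobin genes Hba-a1 (-1.60), Hbb-b2 (-1.33) and Hbb-b1 (-1.25), and Hamp (-1.56), the gene of the iron-regulating hormone hepcidin. They were followed by Pon1 (-1.30), Asgr1 (-1.28), Fabp1 (-1.25) and Hspb1 (-1.18). Adjusted p-values ran from 5.38e-10 for Retnla to 0.000208 for Cxcl3 among these increases and from 0.000648 for Hspa1a to 0.0464 for Fabp1 among the decreases. Hba-a1 lost its call after quantile normalization (adjusted p from 0.00273 to 0.0996 over other scalings), without long-term replicate 1 (adjusted p = 0.0560) and without PBS replicate 2 (0.0538). Fabp1 lost its call with log2(TPM + 0.1) (adjusted p = 0.0849), without the filter (0.0772), at a mean TPM of at least 5 (0.0615), with the replicate block (0.0838) and with any 1 library but PBS replicate 2 left out (0.112 to 0.199). On GRCm38.p6, Retnla is gene 57262, chromosome 16, 48842609 to 48844461. Clca1 is gene 23844, chromosome 3, 145004537 to 145032776. Mmp12 is gene 17381, chromosome 9, 7344397 to 7360461. Hspa1a is gene 193740, chromosome 17, 34969359 to 34972156. Hspa1a and Hspa1b, the haemoglobin genes and Speer4c have close copies between which reads can be shared, so the copy that changed is uncertain.

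The excess of higher genes depended on the scaling and on the fit. As deposited, 15.3% of the changed genes were lower, against 25.9% after median-ratio scaling (1467 higher, 512 lower) and 44.8% after quantile normalization (1426 higher, 1157 lower). After removal of each library's trend with transcript length and GC content, the share was 49.5% (1793 higher, 1757 lower), and 1246 of the 1330 higher and 232 of the 241 lower genes kept their call and direction. The count of changed genes was 779, 874, 996, 851 and 990 without long-term replicates 1, 2 and 3 and PBS replicates 1 and 2 in turn. With short-term replicate 1 left out of the fit, 2148 genes were higher and 1007 lower. With the 2 groups alone these were 2500 and 1381.

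Gene lists fixed in advance grouped these genes, and 29 of 52 lists passed the camera test with its preset correlation, 19 higher and 10 lower. With an estimated correlation between members, camera passed 0 of them (smallest adjusted p = 0.132, 10 with an unadjusted p under 0.05), so the list calls rest on the preset correlation. The second adjusted p of a list, marked estimated, is that with an estimated correlation. Where no count adjusted over the list alone is printed, it was the same as that over all genes. Counts after the length and GC correction, marked corrected, and without single libraries, named by group and replicate number, are printed for lists where those of higher or lower members moved by 2 or more and by over 1.5 times. An adjusted p without a single library is printed where it changed the call of a list. All 9 goblet cell markers rose (median 2.60, adjusted p = 7.11e-16, adjusted p = 0.132 estimated), among them Muc5ac (2.81), a main gel-forming mucin of the airway, Clca1 (6.89) and Gp2 (3.46). Of 16 ciliated cell markers 15 rose and 1 did not pass (median 0.95, adjusted p = 1.56e-13, adjusted p = 0.168 estimated). Foxj1, the transcription factor that directs formation of motile cilia, rose by 1.47 ± 0.12, from 90.3 ± 4.89 to 252 ± 26.8 TPM, and the ciliary genes Rsph1 (1.32) and Tekt1 (1.24) rose as well. Markers of club cells, the secretory cells of the small airways, did not pass as a list (median 0.36, adjusted p = 0.114, adjusted p = 0.706 estimated), with adjusted p from 0.0286 to 0.106 over other scalings. The list rose in 2 of 10, or 3 adjusted over the list alone, and the members that rose, named after their values were seen, were Scgb3a1 (2.61) and Gabrp (0.94).

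Macrophage and inflammatory lists were higher as well. Lysosome and lipid-laden macrophage genes rose in 16 of 26, or 19 adjusted over the list alone (median 1.02, adjusted p = 4.45e-16, adjusted p = 0.202 estimated). Trem2, a lipid-sensing receptor of macrophages, went from 8.59 ± 0.750 to 55.0 ± 4.52 TPM. Alveolar macrophage markers rose in 9 and fell in 1 of 17, or 10 and 1 adjusted over the list alone (median 0.79, adjusted p = 0.000475, adjusted p = 0.389 estimated, 11 higher and 3 lower corrected). Itgax, which encodes the integrin CD11c, rose by 1.90, Plet1 by 1.12 and Ctsk by 3.80. The member that fell was Fabp1, whose call was lost in 5 of the 6 fits without 1 library. Interstitial and monocyte-derived macrophage markers rose in 8 of 20, or 11 with 1 that fell adjusted over the list alone (median 0.63, adjusted p = 9.81e-07, adjusted p = 0.263 estimated), with the complement genes C1qa (1.30) and C1qb (1.38) among the higher. Acute phase and airway defence genes rose in 17 of 23 (median 1.74, adjusted p = 4.45e-16, adjusted p = 0.202 estimated), including Lcn2 (2.53), whose product binds bacterial iron carriers. Chil4 was listed at 0 in all 3 PBS libraries and at 7.99, 4.26 and 10.5 TPM in the long-term libraries, and its close copy Chil3 makes both uncertain. Type 2 immune genes rose in 13 of 19, or 15 with 1 that fell adjusted over the list alone (median 1.73, adjusted p = 2.55e-13, adjusted p = 0.202 estimated, 14 higher and 2 lower corrected). Several also belong to other lists. Acute inflammatory cytokines and chemokines rose in 10 of 26, or 15 adjusted over the list alone (median 0.63, adjusted p = 3.46e-08, adjusted p = 0.389 estimated), with Cxcl3, Ccl3 (2.18) and Ccl2 (2.08), which attract neutrophils and monocytes.

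Cell cycle genes rose in 24 of 29, or 27 adjusted over the list alone (median 1.25, adjusted p = 5.05e-19, adjusted p = 0.263 estimated). Cdk1, the kinase that drives entry into mitosis, went from 1.24 ± 0.370 to 5.85 ± 1.24 TPM, and Cdc20 (1.62) and Plk1 (1.55) also rose. Metal response genes rose in 9 of 14 (median 0.85, adjusted p = 3.19e-09, adjusted p = 0.218 estimated), including the metallothioneins Mt1 (1.88) and Mt2 (2.42), which bind zinc and copper. Complement and coagulation genes rose in 11 of 26 (median 0.37, adjusted p = 6.56e-05, adjusted p = 0.389 estimated, 7 higher without PBS 1), with C3 at 1.06. Ferroptosis and iron genes rose in 5 of 17, or 6 adjusted over the list alone (median 0.35, adjusted p = 0.00282, adjusted p = 0.407 estimated, 3 higher without PBS 1, 2 or 3). Antigen presentation genes rose in 6 of 17 (median 0.37, adjusted p = 0.000520, adjusted p = 0.421 estimated, 3 higher without long-term 1 or PBS 1). Cholesterol synthesis genes rose in 4 of 19, or 6 adjusted over the list alone (median 0.39, adjusted p = 0.00107, adjusted p = 0.614 estimated, 7 higher and 0 lower corrected), with Fdps at 0.93. Surfactant and alveolar lipid genes rose in 3 of 16 (median 0.29, adjusted p = 0.0127, adjusted p = 0.619 estimated), with the desaturase gene Scd1 at 1.76. Dendritic cell markers rose in 3 of 15, or 6 adjusted over the list alone (median 0.35, adjusted p = 0.00314, adjusted p = 0.218 estimated, 5 higher and 0 lower corrected). Alveolar type 2 cell markers rose in 2 of 13, Lcn2 and Chil1 (2.0) (median 0.33, adjusted p = 0.00148, adjusted p = 0.407 estimated, 4 higher and 0 lower corrected). Interferon response genes were called higher (median 0.45, adjusted p = 0.0181, adjusted p = 0.781 estimated, 0 higher without long-term 1 or 2 or PBS 1 or 2, adjusted p = 0.543 and 0.0691 without long-term 1 and PBS 1) although 26 of 28 did not pass singly. None passed in limma adjusted over the list alone. Inflammasome and pyroptosis genes rose in 2 of 12 (median 0.41, adjusted p = 0.0344, adjusted p = 0.656 estimated, 0 higher without long-term 1 or PBS 1, adjusted p = 0.0651 and 0.0778 without long-term 1 and PBS 1), a call lost after the length and GC correction (adjusted p from 0.0170 to 0.0709 over other scalings).

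Lists that were lower held structural and blood cell genes. Capillary and vascular endothelial markers fell in 7 of 18, or 13 adjusted over the list alone (median -0.50, adjusted p = 4.66e-11, adjusted p = 0.202 estimated, 0 higher and 16 lower corrected, 1 to 4 lower without any 1 library), with Egfl7 (-0.62), Ramp2 (-0.60) and the receptor kinase gene Tie1 (-0.52) as examples. Heat shock genes fell in 6 of 15, or 11 adjusted over the list alone (median -0.40, adjusted p = 2.18e-09, adjusted p = 0.244 estimated, 0 higher and 12 lower corrected). Red cell markers fell in 3 of 7, or 4 adjusted over the list alone (median -0.85, adjusted p = 0.000116, adjusted p = 0.276 estimated, 1 lower without PBS 2), with Alas2 (-1.11), which encodes the haem synthesis enzyme of red cells, beside Hba-a1. Haemoglobin transcripts took 1.79%, 2.65% and 3.0% of TPM in the long-term libraries and 5.47%, 7.53% and 4.99% in the PBS libraries. Cardiac muscle markers, which in mouse lung can come from the muscle of the pulmonary veins or from attached heart tissue, fell in 5 of 13, or 8 adjusted over the list alone (median -0.66, adjusted p = 2.04e-07, adjusted p = 0.244 estimated, 0 higher and 9 lower corrected, 0 to 2 lower without long-term 1 or 3 or PBS 1 or 3). Alveolar type 1 cell markers fell in 1 of 12, or 2 adjusted over the list alone (median -0.34, adjusted p = 0.000202, adjusted p = 0.389 estimated, 0 higher and 8 lower corrected), the member past the threshold being Hopx (-0.53). Smooth muscle and pericyte markers fell in 1 of 15, or 3 with 1 that rose adjusted over the list alone (median -0.34, adjusted p = 0.00181, adjusted p = 0.407 estimated, 0 higher and 6 lower corrected), with Pdgfrb at -0.41 (adjusted p from 0.0184 to 0.0514 over other scalings). Mesothelial markers fell in 1 of 7, Wt1 (-0.57) (median -0.43, adjusted p = 0.0262, adjusted p = 0.479 estimated, 0 higher and 6 lower corrected, adjusted p = 0.0539 and 0.0509 without long-term 1 and PBS 2). Hopx, Pdgfrb and Wt1 did not pass with any 1 of the 6 compared libraries left out (adjusted p from 0.0507 to 0.123, 0.0788 to 0.167 and 0.0846 to 0.149), nor did Pdgfrb and Wt1 with the replicate block (adjusted p = 0.0785 and 0.0879), Pdgfrb without the intensity trend (0.0517) or Wt1 with log2(TPM + 0.1) (0.0826). Without long-term replicate 1, Ramp2, Tie1 and Alas2 lost their calls (adjusted p = 0.0645, 0.0673 and 0.0820), as did Tie1 without PBS replicate 1 (0.0619) and Alas2 without PBS replicate 2 (0.0711). TGF-beta signalling genes fell in 4 and rose in 1 of 28, or 5 and 1 adjusted over the list alone (median -0.15, adjusted p = 0.00915, adjusted p = 0.691 estimated, 2 higher and 7 lower corrected, 2 lower without long-term 1 or 2 or PBS 1), including Id1 (-0.74) and Id3 (-0.93). This call was lost after quantile normalization and the length and GC correction (adjusted p from 0.0170 to 0.128 over other scalings). For adipose tissue markers no member passed (median -0.41, adjusted p = 0.0257, adjusted p = 0.669 estimated, 0 higher and 3 lower corrected, adjusted p = 0.0912, 0.0553 and 0.390 without long-term 1, long-term 2 and PBS 3). Skeletal muscle markers rose in 1 and fell in 1 of 7, or 1 and 2 adjusted over the list alone (median -0.41, adjusted p = 0.0368, adjusted p = 0.407 estimated, 1 higher and 4 lower corrected, adjusted p = 0.0988 and 0.130 without long-term 1 and PBS 3). Both calls were lost under each other scaling (adjusted p from 0.0762 to 0.130 over other scalings and adjusted p from 0.0858 to 0.107) and without short-term replicate 1 in the fit (adjusted p = 0.0555 and 0.0790).

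**Figure D2:**
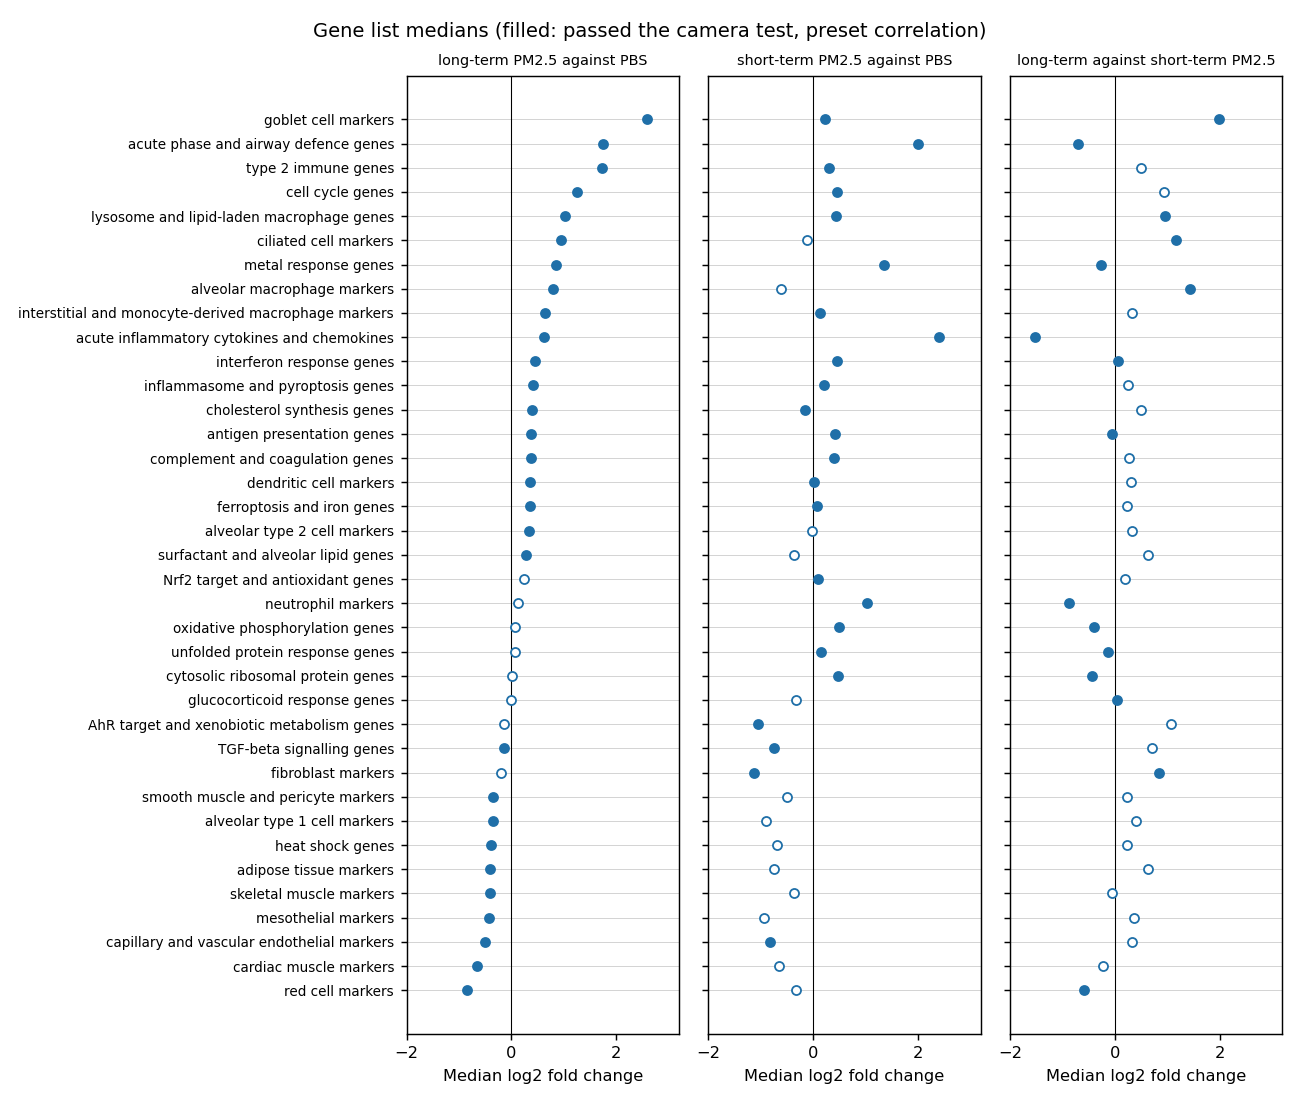
Median log2 fold change (horizontal axis) of gene lists that passed the camera test in at least 1 comparison (vertical axis), in 1 panel per comparison, with filled points for lists that passed with the preset correlation. Goblet cell markers lie at 2.60 in long-term PM2.5 against PBS, while acute inflammatory cytokines and chemokines lie at 2.40 in short-term PM2.5 against PBS and at -1.53 in long-term against short-term PM2.5.

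The Nrf2 target and antioxidant list did not pass between long-term PM2.5 and PBS (median 0.25, adjusted p = 0.0645, adjusted p = 0.706 estimated, 11 higher and 9 lower corrected, 5 higher without any 1 library, 0 lower without long-term 1 or 3 or PBS 1 or 3). Its call depended on the setting, with adjusted p from 0.00203 at a mean TPM of at least 5 to 0.110 without PBS replicate 1. It passed without long-term replicate 1 (0.0390), without PBS replicate 2 (0.0392) and without short-term replicate 1 in the fit (0.0491). Of its 37 tested members 10 rose, 2 fell and 25 did not pass, and 14 rose and 5 fell adjusted over the list alone. Higher members were the cystine transporter gene Slc7a11 (1.06), the glutathione peroxidase gene Gpx2 (1.03), the haem oxygenase gene Hmox1 (0.77) and the glutathione reductase gene Gsr (0.63, adjusted p = 0.0470). Gsr did not pass with any 1 of the 6 compared libraries left out (adjusted p from 0.0793 to 0.175), with log2(TPM + 0.1) (0.0536), without the filter (0.0598), at a mean TPM of at least 5 (0.0574), with the replicate block (0.0956) or without the intensity trend (0.0505). The lower ones, named after their values were seen, were the glutathione transferase genes Gsta1 (-0.80) and Gsta2 (-0.79), which are close copies. Nfe2l2, which encodes Nrf2, was at 113 ± 7.55 TPM with PBS and 125 ± 8.05 TPM with long-term PM2.5 (log2 fold change 0.14 ± 0.22, adjusted p = 0.831), and its value changed sign after the length and GC correction (-0.018). Keap1, whose product holds Nrf2 back, was at -0.033 (adjusted p = 0.934), and the Nrf2 target Nqo1 at 0.21 (adjusted p = 0.613), or -0.014 after the correction. Cyp1a1, induced through the aryl hydrocarbon receptor, did not pass (0.46, adjusted p = 0.353), while Cyp1b1 rose by 1.29.

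Extracellular matrix and fibrosis genes did not pass as a list (median 0.20, adjusted p = 0.0662, adjusted p = 0.842 estimated, 13 higher and 4 lower corrected, adjusted p = 0.0390, 0.0223 and 0.0392 without long-term 1, long-term 3 and PBS 2). With a positive median they passed after median-ratio scaling (adjusted p = 0.0304), quantile normalization (adjusted p = 0.00506) and the length and GC correction (adjusted p = 0.00325), and without short-term replicate 1 in the fit (adjusted p = 0.0435). Of 36 members 5 rose (9 adjusted over the list alone), 1 fell and 30 did not pass. Timp1, an inhibitor of matrix proteases, rose by 2.72 and the secreted phosphoprotein gene Spp1 by 2.35. Col1a1, a chain of type I collagen, rose from 129.7 ± 9.02 to 209 ± 24.5 TPM (0.68 ± 0.12, adjusted p = 0.00433). Acta2, smooth muscle actin and a marker of myofibroblasts, was at -0.061 (adjusted p = 0.849). Fibroblast markers did not pass as a list (median -0.19, adjusted p = 0.144, adjusted p = 0.781 estimated, 3 higher and 6 lower corrected, 0 lower without long-term 1 or 2 or PBS 1 or 3). Of 36 tested genes of a panel of exposure genes fixed in advance, 14 rose (22 adjusted over the list alone) and 22 did not pass. Il6 was among the latter (0.65, adjusted p = 0.132, adjusted p from 0.0337 to 0.349 over other scalings), but passed with log2(TPM + 0.1) (2.17, adjusted p = 0.0188), with the 2 groups alone (adjusted p = 0.0434) and after the length and GC correction.

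**Figure D3:**
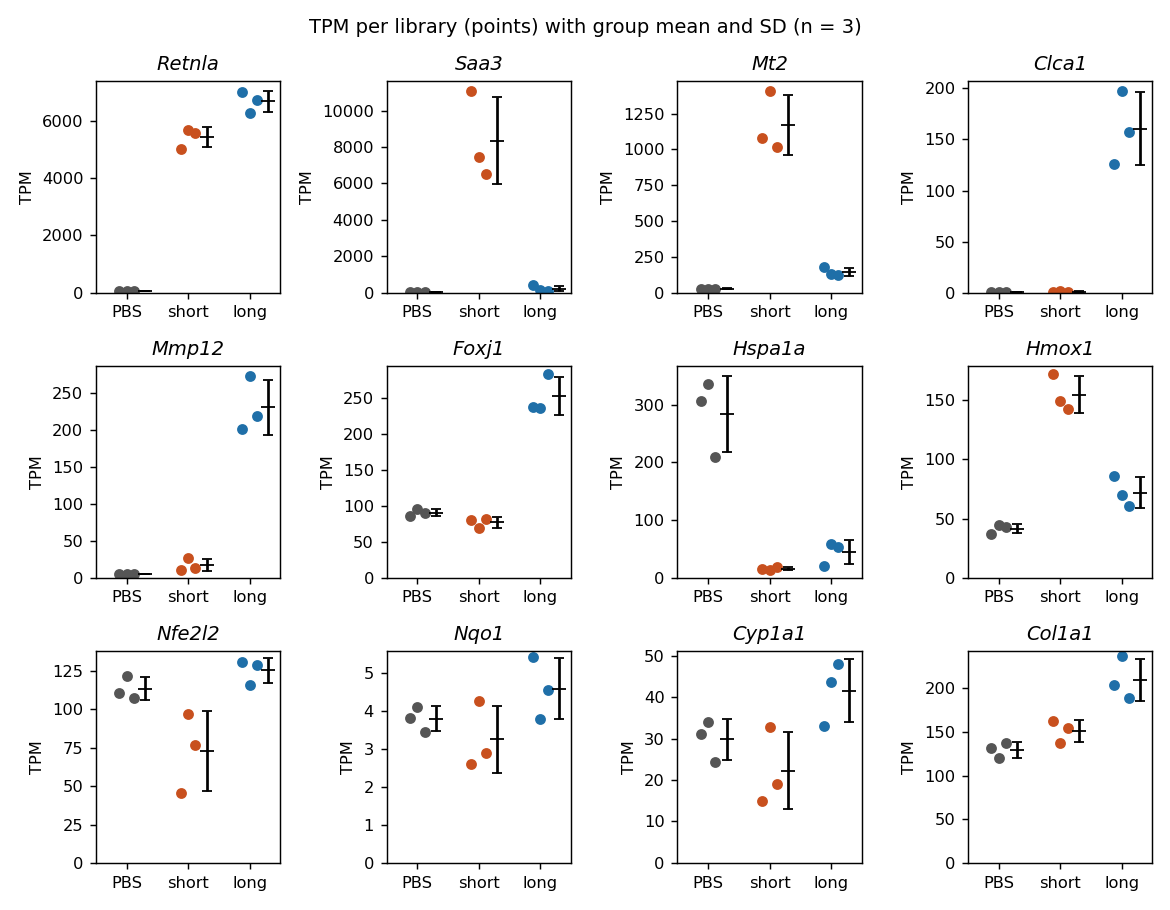
TPM per library (vertical axes, points) of 12 genes in the 3 groups (horizontal axes), with the group mean and SD (n = 3) beside the points. Retnla is high in both PM2.5 groups, Saa3, Mt2 and Hmox1 are highest in the short-term group (8349 ± 2406 TPM for Saa3), Clca1, Mmp12 and Foxj1 in the long-term group (252 ± 26.8 TPM for Foxj1), and Hspa1a in the PBS group.

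Short-term PM2.5 against PBS asked what 1 instillation changed, with the reservation that the PBS label names a long-term exposure. Genes of acute phase proteins, neutrophil-attracting chemokines and metallothioneins were higher in the short-term lungs, and genes of fibroblasts, blood vessels and xenobiotic metabolism were lower. With an estimated correlation the list calls behind this had adjusted p from 0.330 to 0.811, so that none was kept. Saa3, a serum amyloid A protein of the acute phase response, went from 22.4 ± 7.10 TPM with PBS to 8349 ± 2406 TPM (n = 3), a log2 fold change of 8.49 ± 0.40, or 8.84 after median-ratio scaling. Mt2 went from 25.7 ± 3.30 to 1169 ± 209.7, Timp1 from 8.90 ± 1.93 to 610.2 ± 152 and Lcn2 from 274 ± 91.1 to 8556 ± 667 TPM. Retnla was at 5421 ± 353 TPM. Clca1, at 0.737 ± 0.688 TPM, did not pass as deposited (adjusted p = 0.348). It did after the length and GC correction (0.80, adjusted p = 0.00759), a weak call near 0 TPM.

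In this comparison 7268 of 13991 genes changed, 1632 higher and 5636 lower, with 376 and 1838 of them moved by at least 1. The ranges of the groups did not overlap in 7125 of them and in 60.3% of all tested genes. The median log2 fold change of all tested genes was -0.34, and -0.049 after median-ratio scaling. Gene values are therefore given after that scaling unless a standard error stands beside them, and list medians as differences from the median of all genes. The share of lower genes followed this shift, at 77.5% as deposited, 53.2% after median-ratio scaling (3421 higher, 3885 lower) and 51.9% after quantile normalization (3477 higher, 3745 lower). After the length and GC correction it was 52.4% (3252 higher, 3581 lower), with 1318 genes called higher and 3079 lower in both fits and 108 turned from lower to higher. Of the 2756 genes with the shortest transcripts 10.7% were lower, and of the 2753 with the longest 74.7%. The Spearman correlation between length and fold change was -0.56 across genes. Without short-term replicate 1, 1942 genes were higher and 5263 lower. The count was 5585 with the 2 groups alone, 5106 without PBS 1 and 8907 without short-term 2.

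Besides Saa3, the genes with the largest increases were Retnla (7.07), Timp1 (6.27), Saa1 (6.12), Mt2 (5.79), the orosomucoid genes Orm2 (5.61) and Orm1 (5.30), Cxcl3 (5.41), Lcn2 (5.37) and Serpina3n (5.22). Their adjusted p-values in the fit of the values as deposited ran from 8.44e-10 for Retnla to 1.18e-05 for Cxcl3. H2-Q8 aside, the largest decreases were in Hspa1b (-3.97), Hspa1a (-3.74) and the zinc finger gene Zfp366 (-3.06). The extracellular matrix protein gene Abi3bp (-2.79), Trim56 (-2.70), Scube2 (-2.69), Fabp1 (-2.59), Psme2b (-2.57) and Megf9 (-2.52) came next. H2-Q8, a class I histocompatibility gene, was listed at 0 in all 3 short-term libraries, at 91.4, 31.1 and 117 TPM with PBS and at 42.0, 77.3 and 8.65 TPM with long-term PM2.5. H2-Q8 belongs to a family of near-identical genes, as do the Saa, Orm, Serpina3 and Hspa1 genes, and Psme2b is a close copy of Psme2. For all of these the copy that changed is uncertain. On GRCm38.p6, Saa3 is gene 20210, chromosome 7, 46711998 to 46719615. Mt2 is gene 17750, chromosome 8, 94172618 to 94173567. Timp1 is gene 21857, chromosome X, 20870166 to 20874737. Lcn2 is gene 16819, chromosome 2, 32384637 to 32387739.

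Of 52 lists 24 passed the camera test, 20 higher and 4 lower, and camera passed 0 with an estimated correlation (smallest adjusted p = 0.330, 6 with an unadjusted p under 0.05). Acute inflammatory cytokines and chemokines rose in 21 of 26 (median 2.74 from all genes, adjusted p = 3.22e-22, adjusted p = 0.330 estimated). Among them were Ccl3 (4.97), Ccl7 (4.46) and Csf3, which encodes a growth factor of neutrophil production. Csf3 was at 0.0400 ± 0.0346 TPM with PBS and 5.75 ± 0.715 TPM with short-term PM2.5. Il6, an inducer of the acute phase response, went from 0.0700 ± 0.0700 to 7.79 ± 2.56 TPM (log2 fold change 3.0 ± 0.24, adjusted p = 3.08e-05). Acute phase and airway defence genes rose in 18 of 23, or 19 adjusted over the list alone (median 2.34 from all genes, adjusted p = 3.22e-22, adjusted p = 0.330 estimated). Neutrophil markers rose in 13 of 18, or 14 adjusted over the list alone (median 1.38 from all genes, adjusted p = 1.32e-10, adjusted p = 0.400 estimated), with Il1r2 (3.54) and Clec4e (2.82) as examples. Metal response genes rose in 10 and fell in 1 of 14 (median 1.69 from all genes, adjusted p = 2.49e-10, adjusted p = 0.330 estimated), with Mt1 at 3.78. Cell cycle genes rose in 12 of 29, or 11 adjusted over the list alone (median 0.80 from all genes, adjusted p = 4.40e-08, adjusted p = 0.655 estimated, 25 higher and 0 lower corrected), including the replication genes Mcm5 (1.84), Ccne1 (1.46) and Mcm3 (1.35).

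Oxidative phosphorylation genes rose in 27 of 36, or 28 with 1 that fell adjusted over the list alone (median 0.84 from all genes, adjusted p = 3.89e-15, adjusted p = 0.330 estimated, 16 higher and 0 lower corrected, 2 lower without short-term 2), for instance Uqcrq (1.36) and Atp5g1 (1.30). Cytosolic ribosomal protein genes, many of which have pseudogene copies, rose in 23 of 35, or 24 adjusted over the list alone (median 0.81 from all genes, adjusted p = 6.32e-14, adjusted p = 0.522 estimated, 7 higher and 0 lower corrected), for instance Rps2 (1.65) and Rpl18 (1.18). Members of both lists have short transcripts, with median lengths of 933 and 886 nt, and in the short-term libraries genes with short transcripts lay above those with long ones. After the length and GC correction the oxidative phosphorylation list kept its call (median 0.23, adjusted p = 0.00116) and the ribosomal list did not (median 0.10, adjusted p from 3.69e-08 to 0.126 over other scalings). Complement and coagulation genes rose in 11 and fell in 6 of 26 (median 0.73 from all genes, adjusted p = 2.22e-05, adjusted p = 0.522 estimated), with C3 at 2.19 and Cfb, of the alternative pathway, at 2.70. Interferon response genes rose in 9 and fell in 2 of 28, or 7 and 0 adjusted over the list alone (median 0.80 from all genes, adjusted p = 2.69e-05, adjusted p = 0.753 estimated, 13 higher and 0 lower corrected, 5 higher without PBS 1, 0 to 7 lower without any 1 library), with Cxcl10 at 3.44. Type 2 immune genes rose in 8 and fell in 2 of 19 (median 0.64 from all genes, adjusted p = 8.29e-06, adjusted p = 0.522 estimated, 13 higher and 3 lower corrected), with Ccl17 at 3.75. Antigen presentation genes rose in 8 and fell in 1 of 17 (median 0.76 from all genes, adjusted p = 4.83e-06, adjusted p = 0.522 estimated). Lysosome and lipid-laden macrophage genes rose in 12 and fell in 6 of 26, or 13 and 6 adjusted over the list alone (median 0.78 from all genes, adjusted p = 3.65e-05, adjusted p = 0.605 estimated, 3 lower without PBS 3). These calls were lost after quantile normalization, with adjusted p from 0.000506 to 0.0513 over other scalings and adjusted p from 0.000927 to 0.0513 in this order.

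Unfolded protein response genes rose in 6 and fell in 2 of 24, or 6 and 1 adjusted over the list alone (median 0.48 from all genes, adjusted p = 6.54e-05, adjusted p = 0.522 estimated, 17 higher and 3 lower corrected, 11 higher without short-term 1, 5 lower without short-term 2), with the endoplasmic reticulum genes Sdf2l1 (1.87) and Manf (1.57) among the higher. Interstitial and monocyte-derived macrophage markers rose in 8 and fell in 2 of 20 (median 0.47 from all genes, adjusted p = 0.000198, adjusted p = 0.522 estimated, 5 higher without PBS 1, 0 lower without PBS 3). Ferroptosis and iron genes rose in 6 and fell in 1 of 17 (median 0.42 from all genes, adjusted p = 0.00103, adjusted p = 0.522 estimated, 3 lower without short-term 2). Dendritic cell markers rose in 5 and fell in 2 of 15 (median 0.35 from all genes, adjusted p = 0.0110, adjusted p = 0.418 estimated, 6 higher and 0 lower corrected). Inflammasome and pyroptosis genes rose in 5 and fell in 2 of 12, or 5 and 3 adjusted over the list alone (median 0.54 from all genes, adjusted p = 0.0119, adjusted p = 0.669 estimated), with Il1b at 2.51. They lost their call after the length and GC correction (adjusted p from 0.0354 to 0.105 over other scalings). Goblet cell markers rose in 2 of 9, Muc5b (0.98) and Agr2 (1.58) (median 0.58 from all genes, adjusted p = 0.0344, adjusted p = 0.655 estimated, 5 higher and 2 lower corrected, 0 higher without PBS 1, adjusted p = 0.0587, 0.0922 and 0.0544 without short-term 2, PBS 1 and PBS 3). Their call was lost under each other scaling (adjusted p from 0.0557 to 0.117 over other scalings). Muc5b and Agr2 did not pass without PBS replicate 1 (adjusted p = 0.0797 for both), nor Muc5b without short-term replicate 3 (0.0518) or with the 2 groups alone (0.0508). Cholesterol synthesis genes rose in 4 and fell in 3 of 19, or 4 and 1 adjusted over the list alone, and the test was positive (adjusted p = 0.0442, adjusted p = 0.811 estimated, 9 higher and 0 lower corrected, 8 higher without short-term 1, 1 to 7 lower without any 1 library, adjusted p = 0.234, 0.0588 and 0.108 without short-term 2, short-term 3 and PBS 3). Their mean was 0.0085 and their median -0.15 as deposited, but 0.16 after median-ratio scaling, 0.30 after quantile normalization and 0.38 after the length and GC correction.

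Fibroblast markers fell in 12 of 16 (median -0.80 from all genes, adjusted p = 0.00388, adjusted p = 0.669 estimated), with the actin-severing protein gene Gsn (-1.23), Inmt (-0.96) and the fibroblast transcription factor gene Tcf21 (-0.86) as examples. Capillary and vascular endothelial markers fell in 12 of 18, or 12 with 1 that rose adjusted over the list alone (median -0.48 from all genes, adjusted p = 0.0162, adjusted p = 0.669 estimated, adjusted p = 0.108 without short-term 2), with Cdh5 (-0.70), the adhesion protein of endothelial junctions. The call was lost after median-ratio scaling (adjusted p from 2.40e-05 to 0.0524 over other scalings). TGF-beta signalling genes fell in 20 and rose in 1 of 28, or 21 and 3 adjusted over the list alone (median -0.41 from all genes, adjusted p = 0.0316, adjusted p = 0.811 estimated, 5 higher and 11 lower corrected, 3 higher without short-term 1, adjusted p = 0.0587 without short-term 2), with Ltbp4 (-1.12) and Ltbp3 (-0.92), whose products hold latent TGF-beta in the matrix. The call was lost after the length and GC correction (adjusted p from 0.00262 to 0.126 over other scalings). AhR target and xenobiotic metabolism genes fell in 11 and rose in 1 of 17 (median -0.71 from all genes, adjusted p = 0.0363, adjusted p = 0.811 estimated, adjusted p = 0.0661 without PBS 2), with the club cell cytochrome P450 gene Cyp2f2 (-1.39) and Cyp2a5 (-1.43) among the lower and Cyp1b1 (1.72) the member that rose. Extracellular matrix and fibrosis genes fell in 18 and rose in 3 of 36, or 20 and 4 adjusted over the list alone without passing as a list (median -0.17 from all genes, adjusted p = 0.806, adjusted p = 0.945 estimated, 10 higher and 9 lower corrected, 6 higher without short-term 1). Their median was 0.16 after that correction, with a positive test that did not pass (adjusted p from 0.127 to 0.752 over other scalings), and their median transcript length was 4376 nt. Heat shock genes fell in 9 and rose in 1 of 15, or 11 and 1 adjusted over the list alone without passing as a list (median -0.35 from all genes, adjusted p = 0.0614, adjusted p = 0.811 estimated, adjusted p = 0.0139 without PBS 3), with adjusted p from 0.00339 to 0.183 over other scalings.

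The Nrf2 target and antioxidant list moved in both directions after short-term PM2.5. Of 37 members 14 rose, 9 fell and 14 did not pass. Hmox1 went from 41.5 ± 4.03 to 154 ± 15.5 TPM (2.22), Gpx2 rose by 2.13 and the ferritin gene Fth1 by 1.12 (adjusted p from 0.000429 to 0.194 over other scalings). The glutathione synthesis gene Gclm fell by 0.74 and the catalase gene Cat by 0.91. The list was called higher (adjusted p = 0.00528, adjusted p = 0.669 estimated), with a median of 0.094, which is 0.44 from that of all genes, but a mean of -0.016. The call was lost after quantile normalization and after the length and GC correction (adjusted p from 0.0398 to 0.389 over other scalings). The median changed sign without short-term replicate 2 (-0.14), and it was 0.19 without short-term replicate 1 and 0.014 without PBS replicate 2. Nfe2l2 fell from 113 ± 7.55 to 73.0 ± 26.1 TPM (log2 fold change -0.69 ± 0.22, adjusted p = 0.0248), or -0.35 after scaling, where it did not pass (adjusted p from 0.00970 to 0.0730 over other scalings). It did not pass without PBS replicate 1, 2 or 3 either (adjusted p = 0.0606, 0.0788 and 0.0525) or with the 2 groups alone (0.0537). Keap1 (-0.23 as deposited, adjusted p = 0.0911) and Nqo1 (-0.19 as deposited, adjusted p = 0.394) did not pass. Both were positive after median-ratio scaling and quantile normalization, and Keap1 also after the length and GC correction. Cyp1a1 (-0.47 as deposited, adjusted p = 0.148) did not pass, with adjusted p from 0.483 to 0.657 over other scalings, but passed without short-term replicate 2 (-0.77, adjusted p = 0.00527). Col1a1 did not pass as deposited (0.22, adjusted p = 0.143) or after quantile normalization (0.22, adjusted p = 0.106). It rose after median-ratio scaling (0.57, adjusted p = 0.0230) and after the length and GC correction (0.87, adjusted p = 0.000187). Acta2 rose by 0.96 after scaling. In the panel of exposure genes 19 rose (20 adjusted over the list alone), 3 fell and 14 did not pass of 36.

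**Figure D4:**
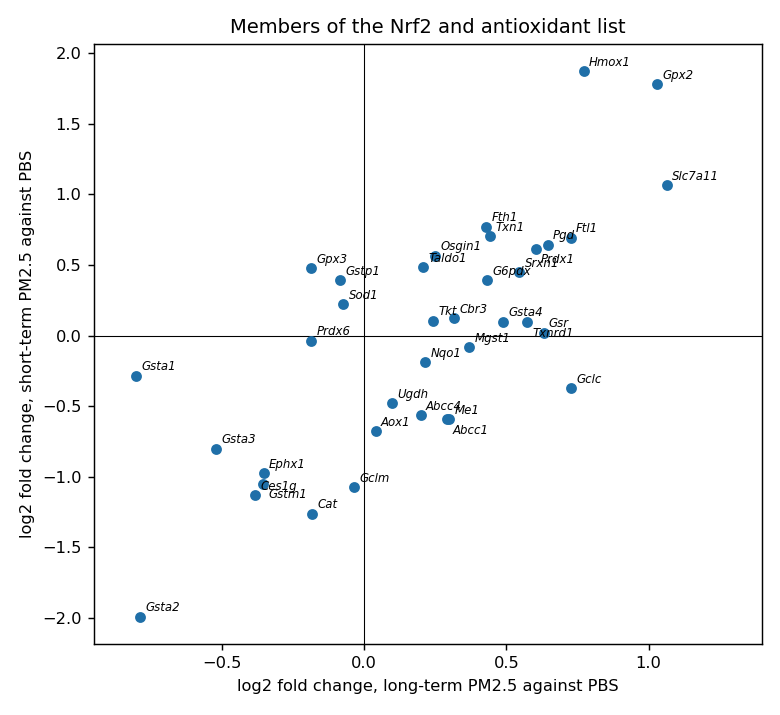
Log2 fold change of each tested member of the Nrf2 target and antioxidant list, long-term PM2.5 against PBS on the horizontal axis and short-term PM2.5 against PBS on the vertical axis, with 1 point per gene. Hmox1 lies at 0.77 and 1.87 and Gpx2 at 1.03 and 1.78, while Cat lies at -0.18 and -1.26 and Gsta2 at -0.79 and -1.99.

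Long-term against short-term PM2.5 compared repeated with single dosing directly. Goblet and ciliated cell genes and those of alveolar and lipid-laden macrophages were higher in the long-term lungs, and acute inflammatory, acute phase and metal response genes were lower than after 1 dose. With an estimated correlation these list calls had adjusted p from 0.289 to 0.780, so that none was kept. Clca1 went from 0.737 ± 0.688 TPM in the short-term to 160.4 ± 35.6 TPM in the long-term group (n = 3), a log2 fold change of 6.58 ± 0.26, or 6.37 after median-ratio scaling. Saa3 was at 225 ± 149 TPM in the long-term group against 8349 ± 2406 TPM, and it fell by 5.76 on the scaled log2 scale. Mcidas and Deup1, which act in the multiplication of centrioles in multiciliated cells, went from 0.523 ± 0.0808 to 11.7 ± 1.01 TPM and from 1.07 ± 0.394 to 17.6 ± 2.29 TPM.

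Here 7061 genes changed, 6070 higher and 991 lower in the long-term group, with 1851 and 128 moved by at least 1, and the count was 4469 without long-term replicate 1. Ranges did not overlap in 6885 of the changed genes and in 60.1% of all tested genes. The median of all genes was 0.41, or 0.078 after median-ratio scaling. As deposited, 14.0% of the changed genes were lower, against 42.3% after that scaling (3762 higher, 2756 lower) and 50.2% after quantile normalization (2977 higher, 2996 lower). The length and GC correction gave 53.6% (2658 higher, 3075 lower). Other large increases were, after scaling, those of Mmp12 (3.41), Gp2 (3.41), Crocc2 (3.13), Chil3 (3.11), the transcription factor gene Myb (3.05), Deup1 (2.92), Mcidas (2.83) and Spata18 (2.69). H2-Q8, listed at 0 in the short-term group, is given no fold. Other large decreases were those of Saa1 (-5.65), Ccl4 (-3.92), Saa2 (-3.61), Timp1 (-3.60) and Hpx (-3.56), the gene of the haem-binding protein hemopexin. Mt2 (-3.41), Ccl7 (-3.40), Il1r2 (-2.95) and Csf3 (-2.87) followed. Adjusted p-values in the fit of the values as deposited were 1.34e-06 for Clca1, 3.23e-05 for Saa3 and 0.000348 for Chil3, and Chil3 and the Saa genes have close copies. On GRCm38.p6, Mcidas is gene 622408, chromosome 13, 112993581 to 113000394. Deup1 is gene 234964, chromosome 9, 15559864 to 15628351.

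Of 52 lists 16 passed, 5 higher and 11 lower, and camera passed 0 with an estimated correlation (smallest adjusted p = 0.289, 7 with an unadjusted p under 0.05). All 16 ciliated cell markers rose (median 0.76 from all genes, adjusted p = 3.64e-06, adjusted p = 0.289 estimated), with Foxj1 at 1.31 after scaling. All 9 goblet cell markers rose (median 1.58 from all genes, adjusted p = 5.68e-06, adjusted p = 0.289 estimated), with Muc5ac at 2.32. Alveolar macrophage markers rose in 15 of 17 (median 1.03 from all genes, adjusted p = 0.00187, adjusted p = 0.747 estimated), for instance Siglecf (1.83). Lysosome and lipid-laden macrophage genes rose in 19 of 26, or 20 adjusted over the list alone (median 0.54 from all genes, adjusted p = 0.00243, adjusted p = 0.780 estimated, 17 higher and 2 lower corrected), for instance Trem2 (1.44). Fibroblast markers rose in all 16 (median 0.43 from all genes, adjusted p = 0.00374, adjusted p = 0.780 estimated, 10 higher and 0 lower corrected), with Col14a1 (1.25) and Gsn (0.69). Acute inflammatory cytokines and chemokines fell in 19 and rose in 1 of 26 (median -1.94 from all genes, adjusted p = 3.70e-23, adjusted p = 0.289 estimated), and Il6 fell by 2.62 after scaling. Neutrophil markers fell in 11 and rose in 1 of 18 (median -1.29 from all genes, adjusted p = 3.75e-12, adjusted p = 0.289 estimated), with S100a9 at -2.01. Acute phase and airway defence genes fell in 14 and rose in 4 of 23 (median -1.12 from all genes, adjusted p = 4.78e-11, adjusted p = 0.289 estimated). Ribosomal protein genes fell in 23 of 35, or 26 adjusted over the list alone (median -0.85 from all genes, adjusted p = 6.36e-20, adjusted p = 0.289 estimated, 0 higher and 15 lower corrected, 10 to 14 lower without long-term 1, 2 or 3). Oxidative phosphorylation genes fell in 23 of 36, or 26 with 1 that rose adjusted over the list alone (median -0.82 from all genes, adjusted p = 6.48e-19, adjusted p = 0.289 estimated, 4 higher without short-term 2, 14 to 15 lower without long-term 2 or 3). After the length and GC correction their medians were -0.31 and -0.33, and both kept their calls (adjusted p = 0.000131 and adjusted p = 6.56e-06).

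Metal response genes fell in 6 and rose in 3 of 14, or 6 and 4 adjusted over the list alone (median -0.67 from all genes, adjusted p = 7.64e-06, adjusted p = 0.401 estimated, 0 higher and 9 lower corrected, 1 higher without long-term 1 or 2), with Mt1 at -1.94. Unfolded protein response genes fell in 8 and rose in 1 of 24 (median -0.55 from all genes, adjusted p = 1.37e-06, adjusted p = 0.401 estimated, 0 higher and 18 lower corrected, 8 higher without short-term 2), with Manf at -1.61. Red cell markers fell in 3 of 7 (median -1.0 from all genes, adjusted p = 0.000284, adjusted p = 0.401 estimated, 0 lower without long-term 1 or short-term 3), with adjusted p from 0.0142 to 0.0885 over other scalings, and haemoglobin transcripts took 5.91%, 3.50% and 6.72% of TPM in the short-term libraries. Interferon response genes were called lower (adjusted p = 0.00243, adjusted p = 0.780 estimated), and of 28 members 2 fell, Cxcl10 (-2.39) and Bst2 (-1.30), with 0 higher and 6 lower corrected, 7 higher without short-term 2, 4 lower without long-term 1 or short-term 3, adjusted p = 0.0680 without long-term 3. Their median was 0.067 as deposited, but -0.27 after median-ratio scaling, -0.35 after quantile normalization and -0.30 after the length and GC correction, where the call was lost (adjusted p from 0.0253 to 0.0545 over other scalings). Antigen presentation genes rose in 2 and fell in 1 of 17 and were called lower (adjusted p = 0.00914, adjusted p = 0.780 estimated, 3 higher and 6 lower corrected, adjusted p = 0.134 without short-term 1), with a mean of 0.049. Their median was -0.058 as deposited, 0.020 after quantile normalization and 0.048 without short-term replicate 1. The call was lost after quantile normalization and after the length and GC correction (adjusted p from 0.0253 to 0.838 over other scalings). Glucocorticoid response genes fell in 4 and rose in 2 of 14, or 2 and 1 adjusted over the list alone and were called lower (adjusted p = 0.0103, adjusted p = 0.780 estimated, 6 higher without short-term 2, 2 lower without long-term 2 or 3 or short-term 2 or 3, adjusted p = 0.0970 without short-term 2), with a mean of -0.18. Their median was 0.044 as deposited, and -0.28, -0.36 and -0.45 after median-ratio scaling, quantile normalization and the length and GC correction, all without a call (adjusted p from 0.0810 to 0.368 over other scalings).

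Nrf2 target and antioxidant genes rose in 13 and fell in 7 of 37, or 13 and 8 adjusted over the list alone, and the list did not pass between the durations (adjusted p = 0.117, adjusted p = 0.780 estimated, 8 higher and 11 lower corrected, 8 higher without long-term 1 or 3, 4 lower without long-term 1, 2 or 3). The test pointed down, while the median was 0.19 and the mean 0.22, and the median was -0.18 after median-ratio scaling. Hmox1 fell by 1.49 after scaling and Gclm rose by 0.66, a call lost after the length and GC correction (adjusted p from 0.000719 to 0.0950 over other scalings). Nfe2l2 rose by 0.84 (adjusted p = 0.0123), or 0.45 after scaling and 0.39 after the length and GC correction. Keap1 (0.20, adjusted p = 0.139) changed sign under each other scaling. Nqo1 (0.40, adjusted p = 0.0842) did so after quantile normalization (-0.21) and passed without short-term replicate 2 (adjusted p = 0.0118). Cyp1a1 rose by 0.93 (adjusted p = 0.0145), or 0.56 after scaling, and Acta2 fell (-1.06). Cyp1a1 lost its call after median-ratio scaling, after the length and GC correction (adjusted p from 0.0497 to 0.0644 over other scalings) and without long-term replicate 3 (adjusted p = 0.0551). Extracellular matrix and fibrosis genes rose in 25 and fell in 1 of 36, or 25 and 2 adjusted over the list alone, without passing as a list (median 0.25 from all genes, adjusted p = 0.108, adjusted p = 0.813 estimated, 11 higher and 5 lower corrected, 3 lower without short-term 1), with adjusted p from 0.000189 to 0.138 over other scalings. Col1a1 rose by 0.46 (adjusted p = 0.0108) but was at 0.076 after scaling and -0.082 after the length and GC correction. It did not pass in either (adjusted p from 0.00543 to 0.744 over other scalings) or without long-term 2 (0.0525). Of 36 exposure panel genes 10 rose (11 adjusted over the list alone), 16 fell and 10 did not pass (4 higher, 19 lower corrected).

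Changes against PBS were compared between the durations, with the limit that both comparisons use the same 3 PBS libraries. Genes higher in both numbered 498, and Retnla, Cxcl3, Lcn2, Mt2 and Timp1 are among them. Independent lists would share 155, and simulated groups without any effect shared 0.020 on average. Groups without effect give hardly any calls, so that overlap was fixed near 0. It does not tell how many of the 498 come from the shared controls. Genes lower in both numbered 200 against 97.1 for independent lists, with Hspa1a and Hspa1b among them. After the length and GC correction 955 were higher in both and 1202 lower in both, against 423 and 457 for independent lists. Genes higher with long-term and lower with short-term PM2.5 numbered 178 against 536 for independent lists. The limma calls held none in the opposite direction as deposited, against 28.1 for independent lists, and 29 after the length and GC correction, against 415. Fold changes had the same sign in 63.8% of genes, and in 66.7% in the simulation. Their Pearson correlation across genes was 0.544, against a mean of 0.501 and a maximum of 0.529 in 100 simulations, and their covariance was 0.163 against 0.0205. With 3 controls the PBS group cannot be split into parts of at least 2, so part of the excess over independent lists may come from the shared controls.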

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

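The tests of scaling by a few abundant genes, of a length and GC trend in each lower gene, of more airway tissue and of handling stress were chosen only after the results they bear on were seen. Lists and genes stand here because they differed directly between long-term and short-term PM2.5 and passed in at least 1 of the comparisons with PBS, and the value given is the median or gene log2 fold change of that comparison as deposited, where the median of all genes was 0.41. Lists called lower after long-term PM2.5 had -1.53 for acute inflammatory cytokines and chemokines, -0.89 for neutrophil markers, -0.71 for acute phase and airway defence genes, -0.59 for red cell markers, -0.44 for cytosolic ribosomal protein genes, -0.41 for oxidative phosphorylation genes, -0.27 for metal response genes and -0.14 for unfolded protein response genes. Interferon response genes (0.067, or -0.30 after the length and GC correction) and antigen presentation genes (-0.058) were also called lower. Glucocorticoid response genes (0.044, or -0.45 after the correction) were called lower between the durations but passed in neither comparison with PBS. Lists called higher had 1.99 for goblet cell markers, 1.44 for alveolar macrophage markers, 1.17 for ciliated cell markers, 0.95 for lysosome and lipid-laden macrophage genes and 0.84 for fibroblast markers. All of these calls used the preset correlation, and the smallest adjusted p with an estimated correlation was 0.289.

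A further 8 genes, those named by rule among 178, rose against PBS with long-term PM2.5 and fell with short-term PM2.5. The difference between the durations was 2.04 for Dnah5 and 1.60 for Dnah9, dynein genes of motile cilia, 3.37 for Crocc2, 3.0 for Spata18 and 3.31 for Myb. It was 2.72 for Scd1 and 0.98 for Fasn, genes of fatty acid synthesis, and 2.14 for Siglecf, a receptor of alveolar macrophages and eosinophils. The decrease with short-term PM2.5 was -0.97 for Dnah5 and -0.78 for Dnah9, which have long transcripts, and after the length and GC correction -0.0035 for Dnah5 and 0.11 for Dnah9. Fasn was at -0.39 with short-term PM2.5 and at 0.42 after the correction. Its rise with long-term PM2.5 did not pass without long-term replicate 2 (adjusted p = 0.0778), PBS replicate 1 (0.0793) or PBS replicate 2 (0.0637).

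In the short-term libraries 5636 genes were lower than with PBS, 10.7% of those with the shortest and 74.7% of those with the longest transcripts, and the share of lower genes among the calls fell from 77.5% to 53.2% after median-ratio scaling, with the median of all genes from -0.34 to -0.049. Scaling set by a few abundant genes as the whole cause is argued against, since the 20 largest gains took 6.28% of TPM and so lower the other genes by 0.094, 0.274 times that median, though the gains of all genes, 19.0%, lower them by 0.30 and leave a shift by many genes open. Of 5563 lower genes of known length 55.3% stayed lower after removal of the fitted transcript length and GC trend. This argues against that trend as their whole cause, not against one the fit missed. The median of all 5563 went from -0.82 to -0.33 (quartiles -0.60 and -0.11). With a simulated trend 0.188% of 1600 stayed lower. The number of lower genes after the removal, 1.02 times that after centring alone, decides nothing, since either step sets higher and lower genes about even (52.4% and 48.8% lower), so the trend stays open for the excess of lower genes and for the 2484 that lost their call. A difference in RNA quality or library preparation, which may have produced the length trend, and the response to the dose both stay open. Without PBS mice of the same duration they were not separated.

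Ciliated and goblet cell markers were called higher in long-term PM2.5 than in PBS at the preset correlation, but not at an estimated one (adjusted p = 0.168 and 0.132). More airway tissue in the long-term samples, with cell types in the same shares, would bring club cell markers along. But the ciliated and goblet medians lay 0.59 and 2.24 above the club cell median. Exact permutations over genes gave p = 0.00525 and 0.00530 (16 and 9 against 10 genes). Genes of a list are not independent, and the permutations are over genes, not over mice. The median of the ciliated markers was 0.84 after the length and GC correction, 0.883 times the uncorrected value, which argues against that trend. More airway tissue with other shares, more ciliated and goblet cells, or higher expression per cell may each underlie the values. Whole lung RNA does not separate them.

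Heat shock genes were called lower than PBS in long-term PM2.5 at the preset but not at an estimated correlation (adjusted p = 0.244), and Hspa1a, Hspa1b and Hspb1 were lower in both PM2.5 groups, where both comparisons share the same 3 PBS libraries. Handling stress in the PBS mice that also induces immediate early genes would lower both lists, but in long-term PM2.5 against PBS the median of the immediate early genes lay 0.44 above that of the heat shock genes (permutation over genes, p = 0.0146, 22 against 15 genes). A trend with transcript length and GC content is argued against by a corrected median of -0.34 in short-term PM2.5 against PBS, with Hspa1a and Hspb1 still lower and past the threshold. A stress of the PBS samples, such as warmth during tissue collection, and an effect of the particles both stay open.

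Other splits of the 6 compared libraries into 3 and 3 were counted for each comparison. The real split was 1 of 10 with as many genes in each, at 1571 genes with a highest other of 9 for long-term PM2.5 against PBS, 7268 with 0 for short-term PM2.5 against PBS, and 7061 with 0 for long-term against short-term PM2.5. These splits are too few for a share under 0.05.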

How the results depend on the processing

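The length and GC correction and its combination with leaving out short-term replicate 1 were chosen only after the results were seen; the other settings were planned. Named genes kept direction and side of the threshold in 4453 of their results over all settings, lost the call in 193, gained one in 16 and changed sign in 15. Counts of called lists stayed within 1.5 times of the value as deposited in 50 of their settings and moved further in 3, those with an estimated correlation, and counts of changed genes stayed within that factor in 40 and moved further in 13. Where values moved or changed sign the cause was not tested, apart from the smaller number of genes or libraries where some were left out. Genes changed between long-term PM2.5 and PBS numbered 920 at a mean TPM of at least 5, where fewer genes were tested. They numbered 2583 after quantile normalization, 3881 with the 2 groups alone and 3550 after the length and GC correction. Leaving out 1 compared library gave 779 (long-term 1) to 1068 (PBS 3). Between the durations it gave 4469 (long-term 1) to 9149 (short-term 2). Array weights, whose estimate had not converged, gave 5273, 11335 and 11345 in the 3 comparisons. With an estimated correlation camera called 0, 0 and 0 lists, with 10, 6 and 7 at an unadjusted p under 0.05. With the replicate number as a block, limma called 1125, 6376 and 6111 genes and camera 30, 23 and 16 lists. Deviations from the group mean correlated between libraries of the same number at -0.29 to 0.26 and of other numbers at -0.27 to 0.34. No pairing showed, but a weak one may exist. The Nrf2 target and antioxidant list median for long-term PM2.5 against PBS was 0.26 with log2(TPM + 0.1) (adjusted p = 0.0382), 0.30 at a mean TPM of at least 5 (adjusted p = 0.00203), 0.21 after quantile normalization (adjusted p = 0.0107), 0.25 with the 2 groups alone (adjusted p = 0.0388) and 0.25 with array weights (adjusted p = 0.0244), all called, and 0.24 (long-term replicate 1) to 0.31 (PBS replicate 3) with 1 library left out. For short-term PM2.5 against PBS the call was lost with an estimated correlation (0.094, adjusted p = 0.669), after quantile normalization (0.10, adjusted p = 0.389), after the length and GC correction (0.16, adjusted p = 0.279) and after that correction without short-term replicate 1 (0.19, adjusted p = 0.205); with 1 library left out the median was -0.14 (short-term replicate 2) to 0.19 (short-term replicate 1). Between the durations it was -0.18 after median-ratio scaling and -0.071 after the length and GC correction without short-term replicate 1. In long-term PM2.5 against PBS, Nfe2l2 was -0.018 and Nqo1 -0.014 after the length and GC correction. In short-term PM2.5 against PBS, Keap1 was 0.11 after median-ratio scaling, 0.0095 after quantile normalization, 0.12 after the length and GC correction and 0.10 after that without short-term replicate 1, Nqo1 was 0.080 after median-ratio scaling and 0.24 after quantile normalization, and Gpx3 was -0.0073 after quantile normalization. Between the durations, Keap1 was -0.18, -0.050, -0.15 and -0.13 in these 4 settings, Nqo1 -0.21 after quantile normalization and Col1a1 -0.082 after the length and GC correction. The correlation of the fold changes was 0.516 without a filter on low values and 0.503 (short-term replicate 2) to 0.578 (short-term replicate 1) with 1 library left out. Depth is unknown, so values near 0 TPM could not be given a detection limit.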

Other observations

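Lists of circadian clock genes and of alveolar type 1 cell and alveolar macrophage markers did not pass in short-term PM2.5 against PBS. The list tests were planned, and the genes named in this part were chosen only after their values were seen. Circadian clock genes fell in 12 and rose in 1 of 18 (median -0.46 from all genes, adjusted p = 0.320, adjusted p = 0.945 with an estimated correlation, 2 higher and 6 lower after the length and GC correction). Their median transcript length was 4106 nt, and genes with long transcripts were lower in the short-term libraries. After median-ratio scaling, Cry1, a repressor of the clock, was at -1.34, Arntl, a clock activator, at -1.05 and Npas2 at -1.07, while Bhlhe40 rose (1.04). The time of day of collection is not given in the sources used here. In long-term PM2.5 against PBS 3 of the 18 rose, Dbp (1.05), Bhlhe40 (0.99) and Bhlhe41 (1.56), and the list did not pass (median -0.21, adjusted p = 0.523, adjusted p = 0.933 with an estimated correlation, 3 higher and 3 lower after the length and GC correction). Alveolar type 1 cell markers fell in 9 and rose in 2 of 12 (median -0.56 from all genes, adjusted p = 0.448, adjusted p = 0.945 with an estimated correlation), with adjusted p from 0.00578 to 0.265 over other scalings. Alveolar macrophage markers fell in 8 and rose in 2 of 17 (median -0.28 from all genes, adjusted p = 0.817, adjusted p = 0.945 with an estimated correlation).

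Lists of immediate early, p53 and DNA damage, epithelial-mesenchymal transition and epithelial junction genes did not pass in short-term PM2.5 against PBS (adjusted p = 0.817, 0.203, 0.289 and 0.448, and adjusted p from 0.811 to 0.945 with an estimated correlation). The last of them had adjusted p from 0.0404 to 0.265 over other scalings. In long-term PM2.5 against PBS the lists of T cell, B cell, NK and cytotoxic cell and plasma cell markers did not pass, with adjusted p = 0.0810, 0.683, 0.0810 and 0.489, and adjusted p from 0.706 to 0.940 with an estimated correlation. T cell markers passed without single libraries (adjusted p = 0.0113 and 0.0283 without long-term 3 and PBS 2), as did NK and cytotoxic cell markers (adjusted p = 0.0265, 0.0205 and 0.0280 without long-term 1, PBS 1 and PBS 2).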
